A study of Mus musculus with 16 samples.

How the data were processed

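Single-cell RNA sequencing (10x Genomics 3' version 3.1 chemistry) was made from microglia with intermediate CD45 and from CD206-positive border-associated macrophages, which are the macrophages of the meninges, perivascular spaces and choroid plexus. Per the labels, the cells were sorted from whole brains of 6-month-old mice. Per the labels' protocols, brains were digested with DNase I, collagenase D and dispase II and passed through a syringe and a strainer, and Percoll, red cell lysis and antibody staining came before the sort. The mice were healthy or carried APP(NL-G-F), a knock-in of a humanised amyloid precursor gene with familial Alzheimer's disease mutations (APP-KI). Each background came as FIT2-WT or FIT2-Mut. FIT2 is the protein of the gene Fitm2, an endoplasmic reticulum membrane protein needed for lipid droplet formation. The labels do not say what the mutation is or how many mice gave each sample.

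The 16 deposited samples fall into 4 groups of 4, numbered as biological replicates in the labels. The deposited values are whole-number UMI counts per gene and cell barcode. The authors made them with Cell Ranger 7.0.0 on mm10, per the submitters' processing notes. Whether intronic reads were counted is not given in the sources used here. The files hold 32285 features, of which 78 share a symbol with another, and the one with most UMIs kept the bare symbol.

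Before the data were examined, the tests, the gene lists, the markers, the rule for named genes and most alternatives were fixed, together with a check of whether the 4 samples of a group were 1 library. Samples of a group were to be taken as 1 library if they shared over 50% of cell barcodes while samples of different groups shared under 5%. All 24 pairs within groups shared 99.9% or more and all 96 pairs across groups 0.16% or less. The samples are therefore called deposits here, each group is 1 library, and n = 1 library per group. Counts were averaged over the 4 deposits on barcodes present in all 4. They were not summed, because 1 molecule can be counted in each deposit.

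Cells with at least 500 genes and at most 10% mitochondrial counts were kept, and barcodes with over 5% haemoglobin UMIs were removed as red cells. Scrublet (expected rate 0.05) called 0 doublets in each library, so it has not worked and no doublets were removed. Removal of the top 5% of its scores in each library was added as an alternative after the data were seen. Cells were clustered with scanpy 1.11.5 and leidenalg 0.10.2 (2000 variable genes, 30 principal components, 15 neighbours, resolution 1, seed 1) under Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3. The MHC class II list and mitochondrial, ribosomal protein, haemoglobin and sex-check genes were left out of the variable genes. Clusters were named from 17 lists of cell type markers. A marker counted as present at 20 CPM or more and at 0.2 or more of its level in the highest cluster, and a name needed at least 5 markers and 0.8 of a list. These scoring rules were set after the clusters were seen, and the shares of clusters they left out are given with the class shares.

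UMI counts were summed per library and class. CPM was computed on the class total. Comparisons of 2 libraries are log2 folds of CPM plus a pseudocount of 5. Their 95% intervals combine exact Poisson limits of both libraries in quadrature and cover counting error only. Genes entered at 20 CPM and 50 UMIs or more in the higher library, and no test was made between 2 libraries. The 1 test possible was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) of an additive model with APP and FIT2 as factors over the 4 libraries. It used rounded averaged counts, filterByExpr, TMM factors and Benjamini-Hochberg adjustment at 0.05. The model leaves 1 residual degree of freedom, and its spread is the departure from additivity. edgeR moderates this spread over genes, with 7.58 prior degrees of freedom in microglia and 9.32 in border-associated macrophages. Nothing in the labels makes the p-values of the model speak for separate mice. DESeq2 1.42.0 was an alternative.

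For pairs of libraries, the 20 gene lists were described by their members at least 1.5-fold apart, and by the percentile of the list's median among 10000 random lists of the same size matched on expression in 20 bins. For the additive test, members past it were counted, also adjusted over the list alone. Named genes were Fitm2, App, the 10 highest and 10 lowest genes of each comparison and class, and up to 4 members of each list with the largest folds, under the same floors. Main effects were ranked by the smaller absolute fold of the 2 backgrounds among genes with the same sign in both, whether or not they passed the test. Genes of the sex chromosomes used to check sex, mitochondrial, ribosomal protein, haemoglobin and unnamed genes were left out of the ranking. Names outside this rule were chosen after their values were seen. Of the genes the rule selects, 2 are not reported here. The total of higher and lower genes, on which alternatives were judged, was chosen after the separate counts were seen.

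Shares of microglia with a UMI of a gene were computed on deposit 1 of each library after thinning every cell to 2500 UMIs, with exact binomial (Clopper-Pearson) intervals at 95%. Fitm2 and App ratios have exact conditional binomial intervals. Positions are those of GENCODE M21 on GRCm38, the assembly that mm10 names. Clec7a and Mx1 were not analysed here.

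The test and the folds were tested on simulated data with known changes of 1.5, 2, 3 and 4-fold, in 50 genes each of at least 50 UMIs per library on average. At the size of the microglia libraries the test recovered 82%, 94%, 100% and 100% of these genes, with 0 false among 188 calls over 13600 genes. At the size of the border-associated macrophage libraries it recovered 44%, 94%, 100% and 100%, with 10 false among 179 calls over 8551 genes. The simulated counts had the spread of the fits (biological coefficient of variation 0.0446 and 0.0693) and no interaction of the factors. Alternatives covered the cell filter, doublets, low counts, size factors, pseudocount, assignment of cells to classes, clustering, summed deposits, single deposits left out, DESeq2 and a model with 1 factor. Figures were drawn with matplotlib 3.10.9.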

Results

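Microglia and border-associated macrophages were profiled in healthy and APP-KI mice that were FIT2-WT or FIT2-Mut, to follow how their transcriptomes differ in an Alzheimer's disease model. The 4 groups are called FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. Each had 4 deposits of 23160344 to 31394636 UMIs and 5132 to 5866 barcodes. The 4 deposits of a group held the same cells, with per-cell totals correlated at 0.9996 or more. Their counts per cell and gene differed by less than the sampling noise, at 0.354 to 0.476 of the Poisson variance, so they were counted as 1 sample. Over genes, chi-square per degree of freedom was 0.405 to 0.989 between deposits of a group and 8.40 to 40.9 between groups. There was therefore 1 library per group, pairwise differences had no replicate check, and the intervals given with them cover counting error only. After filtering, 5415 FIT2-WT, 5553 FIT2-Mut, 5517 APP-KI FIT2-WT and 4851 APP-KI FIT2-Mut cells were kept. Median UMIs per microglial cell were 4332, 4576, 4562 and 4862 in that order. All 4 libraries had a male profile, with the Y-linked gene Ddx3y at 116 to 124 CPM and Xist at 0.226 CPM or less in microglia.

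The targeted genes were examined first. Fitm2 (ENSMUSG00000048486, chromosome 2, 163466379 to 163472629, minus strand, protein coding) was scarce in microglia, at 1.63 CPM (95% interval 1.16 to 2.23) in FIT2-WT and 0.498 CPM (0.264 to 0.857) in FIT2-Mut. In the APP-KI libraries it stood at 1.49 CPM (1.04 to 2.06) in FIT2-WT and 0.582 CPM (0.308 to 1.00) in FIT2-Mut. The Mut over WT ratio was 0.316 (0.154 to 0.606) in healthy mice and 0.402 (0.195 to 0.776) in APP-KI mice. These values rest on 13 to 38 UMIs per library. In edgeR's quasi-likelihood test the fitted log2 fold for FIT2 was -1.48 (SE 0.28), with a Benjamini-Hochberg adjusted p of 0.204 (0.000267 to 1.00 over the alternatives). The counted 3' end may lie outside the mutated part, in which case these counts check nothing about the mutation. In border-associated macrophages Fitm2 had 1 to 3 UMIs per library. App (ENSMUSG00000022892, chromosome 16, 84949685 to 85173766, minus strand, protein coding), the amyloid precursor gene, was at 502 CPM in FIT2-Mut and 411 CPM in APP-KI FIT2-Mut microglia. Its ratios of APP-KI over healthy were 0.878 (0.856 to 0.902) in FIT2-WT and 0.819 (0.797 to 0.841) in FIT2-Mut. For App the fitted fold for APP was -0.18 (SE 0.05, edgeR, Benjamini-Hochberg adjusted p = 0.0353). That call was lost with a 1-factor model or DESeq2 (adjusted p from 0.00641 to 0.199 over the alternatives).

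Most sorted cells were microglia. They made up 90.7% (exact binomial interval 89.9 to 91.5) of kept cells in FIT2-WT, 92.5% (91.8 to 93.2) in FIT2-Mut, 87.2% (86.3 to 88.1) in APP-KI FIT2-WT and 84.5% (83.5 to 85.5) in APP-KI FIT2-Mut. Border-associated macrophages were 2.79% (2.37 to 3.26) and 2.97% (2.54 to 3.45) of cells in the healthy libraries. Their share was higher in the APP-KI libraries, at 6.42% (5.78 to 7.10) in FIT2-WT and 6.31% (5.64 to 7.03) in FIT2-Mut. The sort gate sets these shares, and they come from 1 library each. The 13 microglia clusters held 18966 cells and the 2 border-associated clusters 976. The microglia cluster with most cells was led by Itpkb and Cdk14 in both healthy libraries, by Fos and Nfkbia in APP-KI FIT2-WT and by Gpr84 and Cd14 in APP-KI FIT2-Mut, and microglia values average over all 13. Cells outside both classes were 6.46%, 4.50%, 6.34% and 9.15% in the order above. The largest such cluster, low in UMIs (median 1031.5) and led by Lysmd4 and Ptprj, held 3.08%, 2.23%, 2.76% and 5.57%. A second, with Cst7, Ccl6, ribosomal and mitochondrial genes in the lead, held 0.831%, 0.738%, 1.40% and 1.69%. A cluster of endothelial and mural cells held 1.29%, 1.04%, 0.888% and 0.783%, and a cluster led by Meg3 and Kcnip4 held 1.13%, 0.378%, 1.16% and 0.948%.

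In microglia of APP-KI mice, genes of the disease-associated state, antigen presentation, chemokines and interferon response rose, and Mid1, Mt2 and Klf2 were among the genes that fell. Cst7 (chromosome 2, 150570415 to 150578944), which encodes the protease inhibitor cystatin F, was at 8.73 CPM in FIT2-WT and 103 CPM in APP-KI FIT2-WT. The log2 fold of Cst7 was 2.97 (2.83 to 3.11), and 2.72 (2.59 to 2.86) on the FIT2-Mut background. Apoe (chromosome 7, 19696109 to 19699188), the lipid carrier apolipoprotein E, was higher by 2.10 (2.06 to 2.14) and 1.99 (1.95 to 2.03) on the log2 scale in the same order. The cluster led by Cst7 and Apoe held 47, 40, 405 and 350 cells in FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. Outside it the log2 folds were smaller, 1.55 and 1.29 for Cst7 and 1.34 and 1.15 for Apoe. Il12b, the shared p40 subunit of interleukins 12 and 23, was higher by 2.46 and 3.14, and osteopontin (Spp1) by 1.47 and 1.28. The plot of folds by FIT2 background shows these genes among the 20 ranked highest and lowest.

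**Figure D1:**
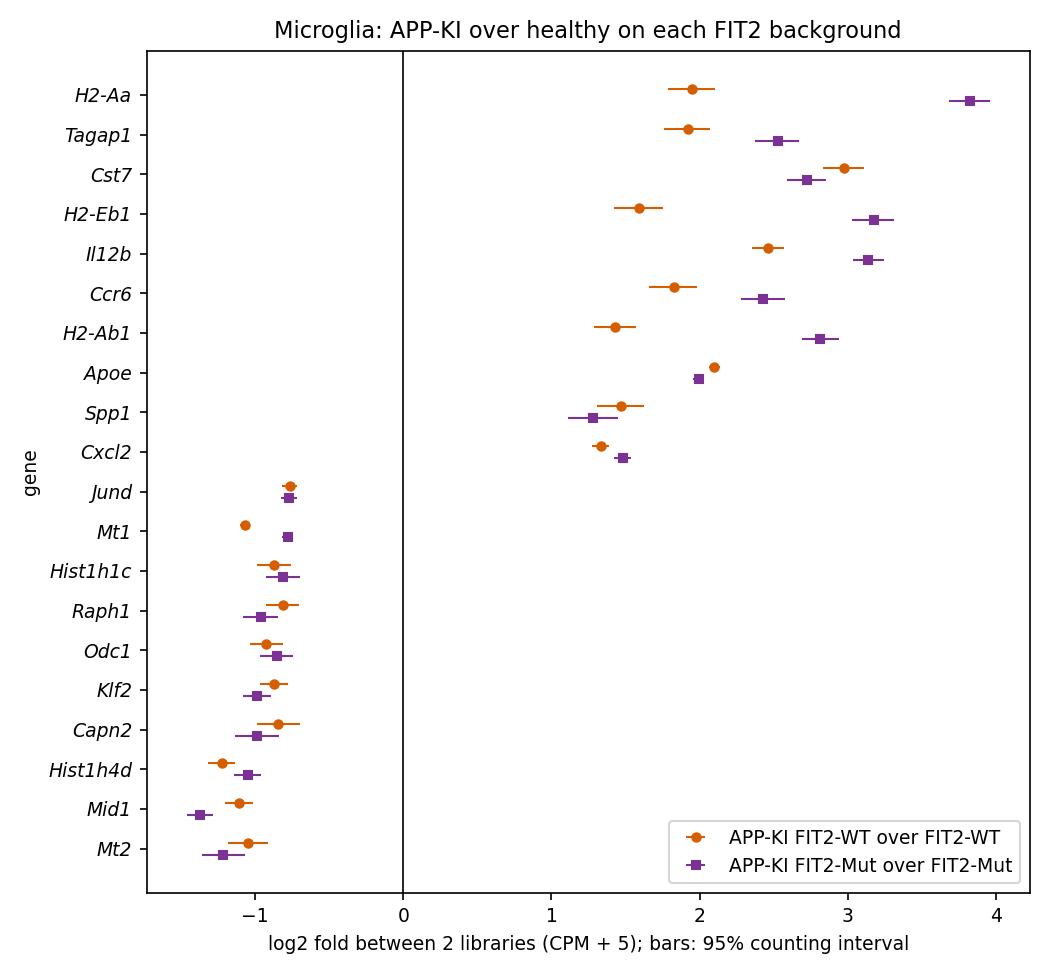
Log2 fold (x axis, CPM plus 5) of the 10 highest and 10 lowest ranked genes (y axis) in microglia of APP-KI over healthy mice, with circles for FIT2-WT and squares for FIT2-Mut and bars for 95% counting intervals. Only genes on the same side of 0 on both backgrounds were ranked, with Cst7 (2.97 and 2.72) first of the highest and Mid1 (-1.11 and -1.37) first of the lowest. The y axis is ordered by the fitted log2 fold, with H2-Aa (4.12) and Mt2 (-1.31) at its ends.

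Tagap1 and Ccr6, both on chromosome 17 (6955011 to 6961156 and 8236043 to 8257141), were higher by 1.92 and 1.82 on the FIT2-WT and by 2.53 and 2.43 on the FIT2-Mut background. The chemokine gene Cxcl2 was higher by 1.33 and 1.48. Among the lowest were the X-linked ubiquitin ligase gene Mid1, the metallothionein genes Mt2 (-1.05 and -1.22) and Mt1 (-1.07 and -0.78), the histone gene Hist1h4d (-1.23 and -1.05), Odc1, the first enzyme of polyamine synthesis (-0.93 and -0.86), and the transcription factor genes Klf2 (-0.87 and -0.99) and Jund (-0.77 and -0.77). All 20 ranked genes passed edgeR's quasi-likelihood test of the APP effect with Benjamini-Hochberg adjustment, with adjusted p from 2.33e-07 for Cst7 and Apoe (fitted log2 folds 3.44, SE 0.08, and 2.13, SE 0.05) to 0.000403 for H2-Ab1. They also passed under each alternative that gave them a value. The ranking used the folds of these same 4 libraries, so the passing of these genes is no separate support.

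The disease-associated list had 22 of 30 tested members higher and 1 lower in this test (24 and 2 adjusted over the list alone). Besides Cst7, Apoe and Spp1 it included Lpl, lipoprotein lipase, and Axl, a receptor for dying cells, with fitted folds of 1.36 and 1.58. Homeostatic microglia genes moved little, with 1 of 18 higher (Fcrls, 0.27) and 2 lower (Mef2c, -0.22, and the purine receptor gene P2ry13, -0.28), the same counts adjusted over the list alone. The type I interferon response list had 18 of 22 higher (20 adjusted over the list alone), such as Ifitm3 (1.08) and Isg15 (0.73). MHC class II had 7 of 10 higher, led by H2-Aa (4.12), H2-Eb1 (3.44), H2-Ab1 (2.62) and the invariant chain gene Cd74 (1.81). MHC class I had 12 of 14 higher, with H2-Q6 (0.71), H2-Q7 (0.70) and H2-M3 (0.67) in front. The counts of both MHC lists were the same adjusted over the list alone. Cytokines and chemokines had 13 of 18 higher (14 adjusted over the list alone), including Cxcl10 (1.27), Ccl5 (1.14) and the interleukin-1 beta gene Il1b (0.95). DESeq2 called fewer in most of these lists, 17 disease-associated, 8 interferon, 5 MHC class II, 10 MHC class I and 11 cytokine genes higher, and 1 homeostatic gene higher and 2 lower.

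Proliferation had 12 of 16 higher and 1 lower (14 and 1 adjusted over the list alone), but DESeq2 called 2 higher and 1 lower. The cluster led by Stmn1, Top2a and Mki67 held 3, 6, 20 and 31 cells in FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. Of the list's 3 members above the floors, the tubulin regulator Stmn1 rose by 1.37 and the tubulin gene Tubb5 by 0.28, and Hmgb2 fell by 0.30. Glycolysis had 11 of 16 higher (12 higher and 1 lower adjusted over the list alone), among them Pkm (0.54), Pfkl (0.51) and the glucose transporter gene Slc2a1 (0.49). The lysosome list had 8 of 24 higher and 2 lower (9 and 2 adjusted over the list alone), from Ctsl (0.69) and Ctsd (0.43), both cathepsins, to Lamp1 (-0.24). DESeq2 called 10 glycolysis and 5 lysosome genes higher and 0 lower (1 and 2 lower unadjusted by edgeR). Lipid droplet and triglyceride turnover genes went both ways, with 4 of 23 higher and 2 lower, as also over the list alone. Hilpda, an inhibitor of triglyceride breakdown, rose by 0.31, the droplet coat gene Plin2 by 0.22 and the hormone-sensitive lipase gene Lipe by 0.33, while Soat1, which esterifies cholesterol, fell by 0.26. DESeq2 called none of these 23.

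Over all genes, 1413 of 13585 were higher and 1356 lower with APP (edgeR quasi-likelihood, Benjamini-Hochberg). DESeq2 called 418 higher and 262 lower. Of the 29 genes at least 2-fold apart between APP-KI FIT2-WT and FIT2-WT (23 higher and 6 lower of 5881), all had the same direction on the FIT2-Mut background and 21 were 2-fold apart there. That background had 22 higher and 6 lower of 5902. The test has 1 residual degree of freedom and no separate mice behind it, so its counts compare these 4 libraries.

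Cells thinned to 2500 UMIs gave the share of microglia with these transcripts. Cst7 was found in 2.04% (1.65 to 2.49) of FIT2-WT and 1.87% (1.5 to 2.30) of FIT2-Mut microglia, against 9.32% (8.47 to 10.2) in APP-KI FIT2-WT and 8.50% (7.64 to 9.43) in APP-KI FIT2-Mut. Unthinned shares were 3.52%, 3.35%, 12.8% and 13.7%. The endothelial and mural cluster, which should lack Cst7, had it in 3 of 90 thinned cells, 3.33% (0.693 to 9.43), so the healthy shares were not above this background, whose wide interval also spans the APP-KI shares. Unthinned, 4 of 215 such cells had Cst7, 1.86% (0.509 to 4.69) at a median of 2185 UMIs, against medians of 4448, 4424.5, 4328 and 5247 in the microglia. Itgax, the integrin CD11c, was found in 1.06%, 1.01%, 2.64% and 2.94% of microglia in the order FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. It was in 0 of those 90 background cells, whose exact upper limit of 4.02% lies above all 4 shares. Unthinned Itgax shares were 2.18%, 2.06%, 4.76% and 6.22%. The division genes Mki67 (0.111%, 0.129%, 0.444% and 0.572%) and Top2a (0.155%, 0.172%, 0.561% and 0.65%) were found in few cells, and their background of 0 of 90 cells, with the same upper limit, does not set these shares apart from free RNA. Their unthinned shares were 0.204%, 0.214%, 0.831% and 1.02% for Mki67 and 0.244%, 0.331%, 0.769% and 1.17% for Top2a. The cluster led by Stmn1, Top2a and Mki67, with 3, 6, 20 and 31 cells, argues against free RNA for those cells. Free RNA would not gather several division genes in the same few cells. Shares of Spp1 were 0.642%, 0.473%, 1.5% and 1.56%, no higher than the 2.22% of the background cells. Ifit3 (1.35%, 0.860%, 1.59% and 2.08%) lay below the 7.78% of the endothelial and mural cells. Free RNA would reach microglia alike, so that 7.78% is no measure of it. A microglia cluster of 365 cells was led by Ifit3, Ifitm3 and Isg15.

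**Figure D2:**
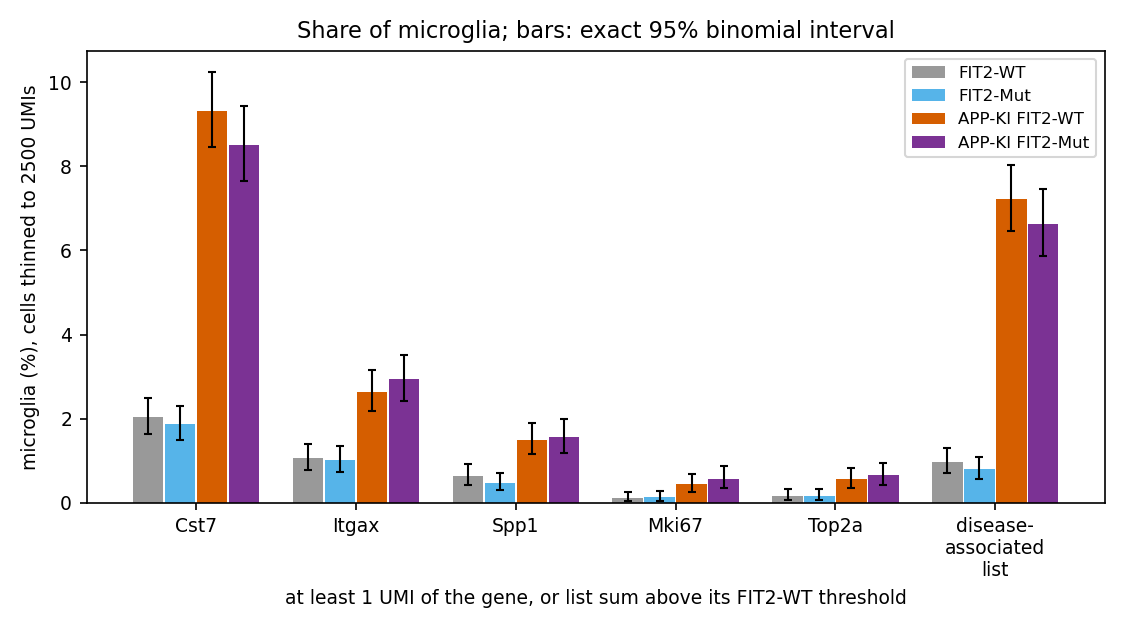
Percent of microglia thinned to 2500 UMIs (y axis, from 0) with a UMI of each gene, or with disease-associated list UMIs above the 99th percentile of FIT2-WT (x axis), as bars for the 4 groups with exact 95% binomial intervals. The list's bars stand at 0.975% and 0.795% in the healthy and at 7.22% and 6.63% in the APP-KI libraries.

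Microglia whose summed UMIs of the disease-associated list exceeded the 99th percentile of FIT2-WT (129 UMIs) are a range of a score and no type. They were 0.975% (0.709 to 1.31) of FIT2-WT, 0.795% (0.560 to 1.09) of FIT2-Mut, 7.22% (6.46 to 8.04) of APP-KI FIT2-WT and 6.63% (5.87 to 7.47) of APP-KI FIT2-Mut microglia. The intervals of the 2 FIT2 genotypes overlapped on each background. Within 13 UMIs of that limit lay 56, 72, 216 and 199 cells, and median list UMIs per cell were 61, 59, 70 and 71. Thinning left out 400, 484, 534 and 256 shallower microglia. Unthinned shares were 1.02%, 0.779%, 4.45% and 6.32%.

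FIT2 genotype went with few differences in microglia. In FIT2-Mut libraries the chemokine genes Ccl5 and Cxcl10 and the mitotic spindle gene Ckap2l rose, and the heat shock gene Hsph1 fell. Ckap2l led a microglia cluster of 1322 cells together with Ccl4, Ccl3 and Il1b. It was not among the leading genes of the cluster led by Stmn1, Top2a and Mki67, so its rise is no measure of division. Ccl5 was at 26.6 CPM in FIT2-WT and 45.2 CPM in FIT2-Mut, log2 fold 0.67 (0.55 to 0.79), and was higher by 0.53 (0.44 to 0.62) among the APP-KI libraries. Cxcl10 was higher by 0.38 (0.31 to 0.45) and 0.62 (0.58 to 0.67) in the same order, Ckap2l by 0.50 and 0.35. The folds of Hsph1 were -0.66 and -0.39. In edgeR's quasi-likelihood test 7 genes of 13585 rose and 4 fell with FIT2-Mut (531 and 468 at an unadjusted p under 0.05), and DESeq2 called 3 and 2. Benjamini-Hochberg adjusted p were 0.0121 for Ccl5 (fitted fold 0.66, SE 0.06), 0.0303 for Ckap2l (0.46, SE 0.05), 0.0453 for Cxcl10 (0.52, SE 0.07) and 0.0477 for Hsph1 (-0.55, SE 0.07). Also past the test, and named after their values were seen, were the B cell chemokine gene Cxcl13 (2.23), the calcium channel gene Cacnb4 (1.79), Gm43305 (1.15), Gm17749 (0.62), the haemoglobin gene Hbb-bs (-1.02) and Gm10503. In FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut, Cxcl13 was at 0.561, 2.31, 0.718 and 3.76 CPM. Cacnb4 was at 0.952, 4.16, 2.52 and 7.62 CPM. Both lay below the floor of 20 CPM set for pairwise folds. The unnamed antisense gene Gm10503 (chromosome 17, 30920338 to 30963220) had 51.5 UMIs in FIT2-WT, 59 in APP-KI FIT2-WT and 0 in both FIT2-Mut libraries, at least 18.6-fold and 17.7-fold lower against a floor of 3 counts per library. The labels do not give the strain backgrounds of the lines, and a strain difference there was not tested. Ckap2l (129268210 to 129297212) and Cacnb4 (52428320 to 52676831) lie on chromosome 2, as Fitm2 does. The other named genes past the test lie on other chromosomes. A difference linked to the Fitm2 locus was not tested either. Summed red cell markers in microglia were at 18.8, 8.87, 33.6 and 17.4 CPM in the order FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut.

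By list, 2 of 18 cytokine and chemokine genes rose with FIT2-Mut (Ccl5 and Cxcl10; 8 adjusted over the list alone). No member of the other 19 lists passed over all genes by edgeR or DESeq2. Adjusted over the list alone, 8 of 14 MHC class I genes were higher (9 unadjusted), with H2-M3 (0.24 and 0.31) and H2-Q6 (0.19 and 0.46) the furthest apart in healthy or APP-KI mice. So were 4 of 10 MHC class II genes (5 unadjusted) and 2 of 22 interferon genes (5 unadjusted), and 6 of 22 immediate early and dissociation genes were lower (6 unadjusted), such as Hspa1a (-0.49 and -0.25). Of the lipid droplet genes 0 of 23 passed by edgeR or DESeq2, with 1 lower at an unadjusted p under 0.05 and over the list alone. No measured lipid droplet gene was 1.5-fold apart in healthy (13 genes) or APP-KI (14 genes) mice. The median log2 fold of that list was -0.02 and -0.03, the 18.9th and 57.7th percentile of random lists. Between healthy libraries, 3 of 5854 genes were at least 2-fold higher in FIT2-Mut (Gm42031, Gm43305 and the ubiquitin ligase gene Fbxl7, 1.13) and 2 lower (Gm11290 and the peptide transporter gene Slc15a2, -1.20). The 3 unnamed models fall outside the rule and were chosen after their values were seen. The FIT2 count depended on the processing. With size factors 3 genes rose and 1 fell, a 1-factor model called 0 (55 and 38 unadjusted), and with single deposits left out the total ran from 0 (without APP-KI FIT2-WT deposit 4 or APP-KI FIT2-Mut deposit 1) to 189 (without APP-KI FIT2-WT deposit 3).

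Of the 10 genes whose APP effect was at least 2-fold apart between FIT2 genotypes, 4 belonged to MHC class II, the molecules that present peptides to CD4 T cells. In APP-KI microglia H2-Aa was at 108 CPM in FIT2-Mut and 33.8 CPM in FIT2-WT, log2 fold 1.54 (1.44 to 1.65). H2-Eb1 stood at 83.3 against 25.5 CPM (1.53, 1.42 to 1.65), H2-Ab1 at 118 against 45.0 CPM (1.30, 1.21 to 1.40) and Cd74 at 801 against 371 CPM (1.10, 1.06 to 1.13). These 4 were all the genes at least 2-fold higher in APP-KI FIT2-Mut than in APP-KI FIT2-WT among 5699, and 0 were lower. Between the healthy libraries Cd74 was at -0.03 (-0.09 to 0.03), and H2-Aa was at 5.06 CPM in FIT2-WT and 2.95 CPM in FIT2-Mut. Of the 4, 0 had the same direction between the healthy libraries.

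**Figure D3:**
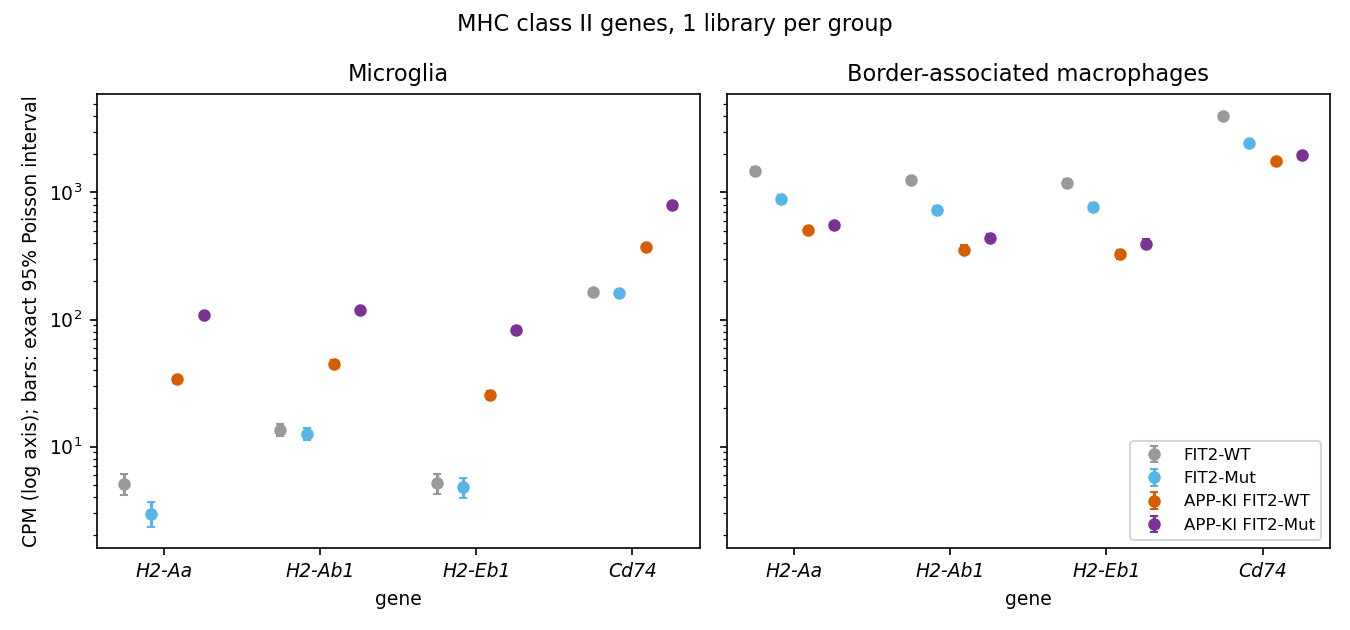
CPM (y axis, log scale) of H2-Aa, H2-Ab1, H2-Eb1 and Cd74 in the 4 groups (x axis) in microglia and in border-associated macrophages, as points with exact 95% Poisson intervals. In microglia the APP-KI FIT2-Mut library has the highest values, and in border-associated macrophages the FIT2-WT library does.

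The APP log2 fold of H2-Aa was larger by 1.88 (1.67 to 2.09) on the FIT2-Mut background, that of H2-Eb1 by 1.58 (1.37 to 1.80), of H2-Ab1 by 1.39 (1.20 to 1.58) and of Cd74 by 1.13 (1.06 to 1.20). The signed difference was also positive for Slc15a2 (1.84, 1.64 to 2.04), the kinase gene Mapkapk3 (1.05, 0.88 to 1.21), the small heat shock gene Hspb1 (0.98) and Il12b (0.68). It was negative for Fbxl7 (-1.19, -1.43 to -0.95) and Pon2 (-0.92). Such a difference need not be a stronger or weaker APP change. Hspb1 fell with APP on the FIT2-WT background (-0.92). Slc15a2 went from 34.1 to 19.9 CPM with APP on FIT2-WT and from 12.03 to 33.9 CPM on FIT2-Mut. Fbxl7 went from 6.96 to 11.6 CPM and from 21.1 to 10.9 CPM in the same order. In total 8 of 5979 genes differed upward by at least 2-fold and 2 downward. Besides those above these were Rpl29 (1.43), Gm11290 (1.85) and Gm42031 (-2.68), which fall outside the rule. Between the APP-KI libraries, chemokine genes Cxcl10 (387 against 250 CPM) and Ccl12 (0.62, 0.57 to 0.66) were also higher in FIT2-Mut, and so was Ifitm3 (0.59). Osteopontin was lower (-0.42, -0.57 to -0.28). List medians lay at the 100th percentile of random lists for MHC class II (0.65), MHC class I (0.25), interferon response (0.23) and cytokines (0.21), at the 99.95th for oxidative phosphorylation (0.06), at the 97.0th for proliferation (0.08, on 3 measured genes) and at the 93.4th for the disease-associated list (0.02). They lay at 0 for glycolysis (-0.12), at 0.045 for homeostatic microglia (-0.09) and at 3.84 for immediate early and dissociation genes (-0.05). Summed border-associated markers in microglia were at 194 CPM in APP-KI FIT2-WT and 165 CPM in APP-KI FIT2-Mut. No test of this difference was possible, because it is the residual of the additive model.

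In border-associated macrophages of APP-KI mice MHC class II genes fell, opposite to microglia, while Il12b, Cst7, amphiregulin (Areg) and 4 of 17 cytokine and chemokine genes rose. H2-Eb1 was at 1184 CPM in FIT2-WT and 326 CPM in APP-KI FIT2-WT, log2 fold -1.85 (-2.0 to -1.70), and at 767 and 396 CPM on the FIT2-Mut background, -0.95 (-1.10 to -0.79). H2-Aa stood at -1.55 (-1.68 to -1.42) and -0.69 (-0.82 to -0.55), and Cd74 at -1.16 (-1.23 to -1.08) and -0.32 (-0.40 to -0.24). Il12b had 0 UMIs in both healthy libraries and was at least 8.41-fold and 9.97-fold higher in APP-KI FIT2-WT and APP-KI FIT2-Mut, against a floor of 3 counts per library. Areg, a ligand of the epidermal growth factor receptor, was higher by 2.32 and 2.25, Cst7 by 2.54 (1.68 to 3.31) and 1.55, Tnfsf9 by 1.5 and 1.65 and the chemerin receptor gene Ccrl2 by 1.25 and 1.15. In APP-KI FIT2-WT and APP-KI FIT2-Mut, Il12b was at 36.2 and 34.9 CPM here against 162 and 240 CPM in microglia. Cst7 was at 69.9 and 20.8 CPM against 103 and 96.6 CPM. Whether microglia RNA in this class gave part of these 2 rises was not tested. At resolution 2, a cluster of 154 cells led by Apoe, Mrc1 and Pf4 carried 10 of 12 microglia markers. Its median was 9070 UMIs, against 3972 to 4245 in this class. It held 14, 28, 61 and 51 cells in FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. Whether its cells are doublets of the 2 cell types, and how many lie in this class, was not tested, which limits each comparison in this class. Among the lowest were Mid1 (-1.02 and -1.04), the transcription factor gene Cebpb (-1.03 and -1.01), Alcam (-1.53 and -0.95), the lamin gene Lmna (-0.86 and -1.01) and the hyaluronan receptor gene Cd44 (-0.92 and -0.81).

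In edgeR's quasi-likelihood test 26 of 8503 genes rose and 51 fell with APP. Benjamini-Hochberg adjusted p were 0.00464 for Il12b, Cst7 (fitted fold 2.83, SE 0.31), Tnfsf9 (1.68, SE 0.17) and Ccrl2 (1.20, SE 0.11), 0.00767 for Areg (2.92, SE 0.36) and 0.00801 for Mid1 (-1.10, SE 0.14) and H2-Eb1 (-1.44, SE 0.19). MHC class II had 3 of 8 tested members lower (H2-Aa, H2-Ab1 and H2-Eb1; 5 adjusted over the list alone) and 0 higher, also unadjusted, while DESeq2 called none of the 8. Cytokines and chemokines had 4 of 17 higher (Tnf, 0.76, Ccl4, 0.72, Ccl3, 0.70, and Il1a, 0.56; 7 higher and 2 lower adjusted over the list alone). The interferon list had 2 of 21 higher (Ifitm3, 0.61, and Ifit2, 3.14, the last named after its value was seen; 8 and 1 adjusted over the list alone), and the disease-associated list 1 of 29 (Cst7; 6 adjusted over the list alone). Of the core genes of these macrophages, 1 of 19 fell (the chemokine gene Ccl24, -0.61), as also adjusted over the list alone. DESeq2 called 2 of these cytokine genes higher and 0 members of the interferon, disease-associated and core lists (unadjusted by edgeR 9 higher and 1 lower, 9 and 0, and 2 and 1). In this class summed border-associated macrophage markers were at 14614, 12636, 12651 and 12305 CPM and summed microglia markers at 3474, 4790, 4750 and 4992 CPM, in the order FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. On the FIT2-WT background 45 of 4119 genes were at least 2-fold higher and 16 lower, and 48 of these 61 had the same direction on the FIT2-Mut background, which had 15 higher and 6 lower of 3920. The classes held 151, 165, 354 and 306 cells. With size factors 4 genes rose and 1 fell and H2-Eb1 had an adjusted p of 0.0604 by edgeR. Without FIT2-WT deposit 4 the total was 22 and H2-Eb1 had 0.0547, and over all alternatives H2-Eb1 ranged from 1.47e-32 to 0.163. Size factors also moved the median log2 fold of all genes between APP-KI FIT2-WT and FIT2-WT from 0.13 to 0.07, and the 2-fold counts to 32 higher and 21 lower.

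With FIT2-Mut, border-associated macrophages had more Cxcl10 and less Areg and Cst7. Cxcl10 was at 18.7 CPM in FIT2-WT and 91.0 CPM in FIT2-Mut, log2 fold 2.02 (1.30 to 2.75), and higher by 1.33 (1.02 to 1.65) among the APP-KI libraries. Areg was at -1.90 in healthy mice, on 11 and 0.5 UMIs, and at -1.97 (-2.41 to -1.53) in APP-KI mice. Cst7 stood at -0.55 and -1.54 (-2.0 to -1.08). These 3 were the genes past edgeR's quasi-likelihood test of 8503 (216 higher and 198 lower unadjusted), with Benjamini-Hochberg adjusted p of 0.0128, 0.0128 and 0.0242 and fitted folds of 1.60 (SE 0.18), -2.25 (SE 0.25) and -1.66 (SE 0.20). Of the 3, Cst7 lies on chromosome 2, as Fitm2 does, and Cxcl10 and Areg lie on chromosome 5. A difference linked to the Fitm2 locus was not tested. In healthy mice 4 of 6 measured MHC class II genes were at least 1.5-fold lower in FIT2-Mut and 0 higher, with H2-Ab1 at -0.77 (-0.92 to -0.62) and H2-Aa at -0.73 (-0.87 to -0.60). In APP-KI mice 0 of 6 were apart, and the list median was 0.21. Homeostatic microglia genes had 5 of 15 at least 1.5-fold higher in healthy FIT2-Mut, such as Sparc (0.92, 0.69 to 1.15), beside the higher microglia markers given above. Heat shock genes Hspa1b (-1.37, -1.69 to -1.05) and Hsph1 (-1.23) were lower, and the growth factor gene Csf1 higher (1.58, 1.05 to 2.13). In APP-KI mice Rnd3 (1.79), Cxcl10 and Ckap2l (1.20) were at least 2-fold higher in FIT2-Mut, and Ly6a (-1.99), Areg, Cst7 and Auts2 (-1.37) lower, among 5083 genes. Healthy mice had 14 higher and 8 lower of 2756 (11 and 10 with size factors). The difference of APP effects was at least 2-fold upward for 23 and downward for 38 of 5119 genes (30 and 30 with size factors), from Ctla2a (2.67, 1.84 to 3.51) to Ly6a (-2.24, -3.41 to -0.99), and was not tested. All 3 calls were lost with size factors (adjusted p = 0.126 each by edgeR), in a 1-factor model, without FIT2-WT deposit 4 (0.177) and by DESeq2, which called 0. Over all alternatives their adjusted p ran from 7.53e-19, 6.94e-20 and 8.91e-09 to 1.00.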

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

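The 3 patterns weighed here were chosen after the results were seen, and the tests of border-associated macrophages among the microglia, of microglia in the border-associated class and of its clusters on the FIT2-Mut background were written after them.

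MHC class II genes went opposite ways in the 2 cell classes of APP-KI mice, and the difference was not tested, since each side is 1 library. The log2 fold in microglia minus that in border-associated macrophages was 3.23 for H2-Ab1, 3.50 for H2-Aa and 3.44 for H2-Eb1 on the FIT2-WT background. On the FIT2-Mut background it was 3.54 for H2-Ab1, 4.51 for H2-Aa and 4.12 for H2-Eb1.

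The MHC class II genes that were higher in APP-KI FIT2-Mut than in APP-KI FIT2-WT microglia were weighed against other cells and free RNA. Border-associated macrophages would have had to give 15.7% of the RNA and raise their summed markers by 1927 CPM, while the markers were 165 CPM against 194 CPM, an observed over needed difference of -0.0149. Free RNA would have raised these genes in endothelial and mural cells too, where they were at 10.4 CPM (1.25 UMIs) in APP-KI FIT2-Mut and 128 CPM (23.75 UMIs) in APP-KI FIT2-WT, a difference of -0.185 of that in microglia. Dendritic or B cells would lack microglia markers, but microglia with at least 2 MHC class II UMIs kept 0.939 of the marker share of the others and made up 0.550%, 0.681%, 3.39% and 8.34% of microglia in FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut. Doublets of microglia with such cells would keep these markers and stay open, as does a minority of such cells. The MHC class II cells had a median of 6002 UMIs against 4764 for the others in APP-KI FIT2-Mut, and 5400 against 4527 in APP-KI FIT2-WT. A limit in UMIs can pick deeper cells by itself. An effect of FIT2 genotype in APP-KI mice stays open, and so do differences between the mice of 2 single libraries and a strain difference near Gm10503 on chromosome 17, all untested, although Cd74 lies on chromosome 18 and none of the 4 genes had a higher CPM in healthy FIT2-Mut than in FIT2-WT.

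The MHC class II genes that were lower in APP-KI border-associated macrophages were weighed against the makeup of that class. Another mix of its 2 clusters is argued against by the median log2 fold within each, on FIT2-WT -1.69 and -1.40 against -1.67 in the class (smaller ratio 0.836) and on FIT2-Mut -0.64 and -0.69 against -0.70 (0.915). The clusters were made without the MHC class II genes, so a shift between cells high and low in these genes could lie within each cluster. Such a shift stays open. More microglia in the class would shift the summed markers, which did go that way on FIT2-WT, from 3474 to 4750 CPM for microglia and from 14614 to 12651 CPM for the class, but by at most 0.192 of what the loss needs (70.9% microglia RNA), and by 0.0585 on FIT2-Mut. Leaving out the 5% of cells with the highest MHC class II share gave 1.95 times the fold on FIT2-WT, which decides nothing, since it takes more of the signal where fewer cells are positive (H2-Aa in 25.2% and 21.8% of healthy against 14.1% and 14.4% of APP-KI cells on FIT2-WT and FIT2-Mut), so a few cells with very high counts stay open. An effect of APP and differences between single libraries also stay open, the more so as the fold was smaller on FIT2-Mut, whose healthy library was already lower in 4 of 6 measured MHC class II genes.

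Tagap1 and Ccr6, both on chromosome 17, were higher in both APP-KI libraries. App and Fitm2 lie on chromosomes 16 and 2. A candidate explanation is a variant linked to another locus that acts in all microglia alike, and outside the Cst7 and Apoe cluster the log2 folds were 1.03 or more of those in all microglia, while healthy libraries had 0 to 2.25 UMIs of each inside it. Inside that cluster the folds on FIT2-WT and FIT2-Mut were 2.11 (0.20 to 2.46) and 2.29 (0.16 to 2.64) for Ccr6. For Tagap1 they were 0.05 (-1.32 to 1.21) and 1.5 (-0.38 to 2.15), with intervals below 1.92 and 2.53 in all microglia. With Tagap1 at 8.57 and 15.4 CPM there in APP-KI mice, the pseudocount keeps its folds below these values whatever the healthy level. The folds of Tagap1 inside the cluster therefore cannot decide, and the explanation stays undecided. Both genes were also higher in APP-KI FIT2-Mut than in APP-KI FIT2-WT, by 0.64 and 0.58, which a variant shared by both libraries does not predict. In APP-KI mice Tagap1 was lower inside that cluster than outside it, at 8.57 against 22.3 CPM (FIT2-WT) and 15.4 against 37.7 CPM (FIT2-Mut), and a response to amyloid stays open, untested.

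Transcripts of pituitary hormones appeared in the APP-KI FIT2-WT library, outside the comparisons made. Growth hormone (Gh) was at 24.6 CPM of the whole library, and prolactin (Prl) at 465 CPM, against at most 0.489 and 0.0369 CPM in the other libraries. Prl reached at least 1 UMI, averaged over the deposits, in 3 of 5517 cells, and Gh in 104. A single cell held 74.6% of Prl UMIs, and a single cell held 53.7% of Gh UMIs. The top 10 cells held 99.7% for Prl and 57.3% for Gh.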

How the results depend on the processing

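Of the alternatives here, removal of the top 5% of doublet scores, the nuclear-poor cluster counted as microglia, other deposits as the molecule table, and class shares by cell were chosen only after the data were seen. No paired analysis was possible because the deposits of a group are 1 library, so their numbers pair no samples. Keeping doublets changed nothing, since none were called. Where values moved, the cause was not tested, except that another filter on low counts changes which genes are counted, and summed deposits bring more genes over the floor of 50 UMIs.

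The 20 ranked genes of the APP effect in microglia, chosen by their folds in these same libraries, passed under each alternative that gave them a value. The total of 2769 genes past the test became 2471 to 3728 with single deposits left out, 1263 with a floor of 50 CPM and 680 with DESeq2. Genes at least 2-fold apart went from 29 to 11 and from 28 to 18 with a pseudocount of 20 CPM on the FIT2-WT and FIT2-Mut backgrounds. Between healthy FIT2 genotypes 5 became 1 with a floor of 50 CPM and 1 with a pseudocount of 20 CPM, and the difference of APP effects went from 10 to 17 with no filter on low counts.

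The microglia FIT2 effect (11 genes) gave 243 with no filter, 0 with a floor of 50 CPM (201 higher and 139 lower unadjusted, edgeR), 4 with size factors, 0 with 1 factor (55 and 38 unadjusted), 40 without the top 5% of doublet scores, 7 with the nuclear-poor cluster, 23 with summed deposits and 5 with DESeq2. Single deposits left out gave 0 to 189. The third way to pair the 4 libraries, which is neither APP nor FIT2, also gave 0 in a 1-factor model in both classes (54 and 46 unadjusted in microglia, 73 and 78 in border-associated macrophages).

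In border-associated macrophages the APP effect (77 genes) gave 243 with no filter, 269 with a floor of 50 CPM, 5 with size factors, 130 with 1 factor, 167 with the strict cell filter, 229 with classes per cell, 144 with summed deposits and 20 with DESeq2. Single deposits left out gave 22 (without FIT2-WT deposit 4) to 299 (without APP-KI FIT2-Mut deposit 2). The FIT2 effect (3 genes) gave 41, 39, 0 (204 and 178 unadjusted), 0 (109 and 118 unadjusted), 6, 27, 5 and 0 (17 and 8 unadjusted) under the same alternatives, 14 without the top 5% of doublet scores, and 0 to 43 with the same deposits left out.

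Pairwise 2-fold counts in this class are given in the order APP on FIT2-WT (61), APP on FIT2-Mut (21), FIT2 in healthy (22), FIT2 in APP-KI (7) and difference (61). With no filter they were 202, 129, 235, 20 and 459, and with a pseudocount of 20 CPM 29, 8, 9, 4 and 21. With a floor of 50 CPM APP on FIT2-WT gave 38, FIT2 in APP-KI 3 and the difference 31. Summed deposits gave 108, 49, 82 and 141 for all but FIT2 in APP-KI, and a pseudocount of 1 CPM gave 117 for the difference. Classes per cell gave 13 for FIT2 in healthy and 12 (0 higher) for FIT2 in APP-KI mice, and 12 came without the top 5% of doublet scores. Classes per cell turned the log2 fold of Slc7a11 to -1.25 (APP on FIT2-WT) and its difference to 0.56, Abcc5 to 0.0315 (APP on FIT2-Mut), Klf12 to -0.10 (FIT2 in healthy) and Zc3h12c to -0.27 (FIT2 in APP-KI). Of the named pairwise values under all alternatives 4440 stayed within their 95% interval, 195 lay outside it and 5 changed sign. Of the named values of the test 2019 kept their side of the threshold, 262 were newly past it and 89 no longer past it, all in the same direction. Of list values 557 stayed and 51 moved, and of thinned shares 99 and 41. Genes under a stricter filter had no value there.

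Microglia shares moved to 88.7%, 91.2%, 85.5% and 81.6% with the loose cell filter, to 94.9%, 95.4%, 91.2% and 90.8% with the strict one and to 86.7%, 88.0%, 76.3% and 72.7% at resolution 2, and to 88.2% in APP-KI FIT2-WT with classes per cell. Border-associated shares in FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut were 2.47%, 5.28% and 5.17% at resolution 2 and 2.41%, 5.44% and 5.36% with classes per cell, and in the latter 2 groups 5.63% and 5.52% without the top 5% of doublet scores. The share above the disease-associated limit was 1.10% in FIT2-Mut at 1250 UMIs, 4.45% in APP-KI FIT2-WT unthinned, 8.15% and 7.86% in the APP-KI libraries with deposit 2 and 6.26% in APP-KI FIT2-WT with deposit 4. Depth limits border-associated macrophages most, with 687150 to 1843800 UMIs of tested genes per library against 21898000 to 25563000 in microglia.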

Other observations

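The tests and lists of this part were fixed before the data were examined, no alternative in it was chosen later, and the members and single genes named were chosen after their values were seen.

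In microglia of APP-KI mice the remaining lists moved in part, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Complement had 6 of 10 members higher (6 higher and 1 lower adjusted over the list alone), with C5ar1, the receptor for C5a, at a fitted log2 fold of 0.32 and C1qa at 0.20. Phagocytosis receptors had 5 of 14 higher and 1 lower (6 and 1 adjusted over the list alone), including Axl (1.58), the lipopolysaccharide co-receptor gene Cd14 (0.67) and Mertk (-0.16). Cholesterol efflux and LXR targets had 5 of 13 higher and 1 lower, among them Apoe (2.13), the exporter gene Abca1 (0.38) and the lysosomal cholesterol transporter gene Npc1 (-0.20). Cholesterol biosynthesis had 3 of 21 higher and 1 lower, with Insig1 at 0.49 and Msmo1 at -0.61. Fatty acid synthesis had 1 of 10 higher (Acaca, 0.72) and fatty acid oxidation 2 of 16 higher (Slc25a20, 0.38, and Ppard, 0.17). These 4 lists had the same counts adjusted over the list alone, and DESeq2 called 2, 1, 1 and 0 of their members in that order. Endoplasmic reticulum stress had 4 of 22 higher and 3 lower (6 and 3 adjusted over the list alone), from Sdf2l1 (0.43) to Ddit3 (-0.52). Oxidative phosphorylation had 4 of 18 higher and 3 lower (5 and 4 adjusted over the list alone), such as Uqcrh (0.24) and Cox7c (-0.31). Immediate early and dissociation genes had 6 of 22 higher and 7 lower (8 and 7 adjusted over the list alone), such as Nfkbiz (0.54) and Klf2 (-0.94). Core genes of border-associated macrophages had 4 of 13 higher and 2 lower in microglia (6 and 3 adjusted over the list alone), namely Ccl8 (3.53), F13a1 (2.75), Pf4 (2.01), Mrc1 (1.25), Maf (-0.19) and Dab2 (-0.57). DESeq2 called 0 of these 13 (6 higher and 3 lower unadjusted by edgeR). In the other lists DESeq2 called 2 complement genes and 4 phagocytosis receptors higher, 3 endoplasmic reticulum stress genes higher and 2 lower, 1 oxidative phosphorylation gene higher and 1 lower, and 5 immediate early and dissociation genes higher and 4 lower. The summed markers of border-associated macrophages were at 181, 189, 194 and 165 CPM in FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut microglia.

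Some single genes stood out. Mid1, on the X chromosome (169685199 to 170005736), had a lower level in APP-KI than in healthy mice in microglia (-1.11 and -1.37) and in border-associated macrophages (-1.02 and -1.04). Slc15a2 was at 34.1 CPM in FIT2-WT, 12 CPM in FIT2-Mut, 19.9 CPM in APP-KI FIT2-WT and 33.9 CPM in APP-KI FIT2-Mut microglia. The unnamed gene Gm42031 (chromosome 8, 85125872 to 85132289) was at 62.6 CPM in FIT2-Mut microglia and at 3.14, 7.48 and 11.1 CPM in FIT2-WT, APP-KI FIT2-WT and APP-KI FIT2-Mut. The levels of Rnd3 in border-associated macrophages were 6.82, 14.3, 4.95 and 29.5 CPM in the order FIT2-WT, FIT2-Mut, APP-KI FIT2-WT and APP-KI FIT2-Mut.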
